A study of Mus musculus with 14 samples.

How the data were processed

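The samples are mouse embryonic stem cells (ESCs) of the C57BL/6 background, grown in serum with leukemia inhibitory factor and inhibitors of the MEK and GSK3 kinases. Per the labels, the series holds 14 samples in 8 groups. They are pull-downs of chromatin with the TALE proteins called TALE 1 (2 samples) and TALE 2 (2 samples), their input (1 sample), chromatin immunoprecipitation (ChIP) of HA-tagged RCOR2 (2 samples) with its negative control (2 samples), ATAC-seq (1 sample), and RNA-seq of Rcor2 knockout (KO) cells (2 samples) and wild-type (WT) cells (2 samples). The files analysed were a table of gene counts for the 4 RNA-seq libraries and 3 peak lists. The input, negative control and ATAC-seq samples were not analysed here on their own. The ChIP replicates differ in sequencing, per the labels' protocols: the first pair of ChIP and control was read single-end on another Illumina instrument than the second, which was paired-end, and the controls were WT cells in one and mCherry-expressing cells in the other.

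The RNA-seq values are raw read counts per gene symbol, as deposited by the authors. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, SAMtools 1.8, Subread and featureCounts for the series, with the mouse builds GRCm38 and mm10, without saying which step each served. Per the labels' protocols, a 19 bp read was used for demultiplexing and a 72 bp read was sequenced from the other end. Whether molecular identifiers were collapsed, whether counting used strand, and how reads shared by near-identical gene copies were counted are not given in the sources used here, so values of histone genes and of genes with processed pseudogenes, such as Gapdh, are uncertain. The columns of the table were identical to the counts deposited for each library. Of 25131 rows, 26 carry a calendar date in place of a gene symbol; they hold 0.136% to 0.158% of the counts and were tested but not named.

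The peak lists give a position, a fold enrichment and a −log10 q value per peak. The fold is the ratio of the pull-down to its control at the peak summit and the −log10 q is the significance, both as the authors deposited them from the peak caller; the submitters' processing notes name MACS2 2.1.1.20160309, Bowtie2 2.3.4.1, bedtools 2.25.0 and HOMER. These values were used only to describe, rank and filter peaks within a list. The peak names of the RCOR2 list show that it was called on merged libraries, so replicates could not be compared, and the control used for each call is not given in the sources used here. The RCOR2 list holds 1 peak on an added contig named for the HA-tagged Rcor2 construct, which was set apart from the 53366 peaks on chromosomes. Positions are 1-based on GRCm38.

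Gene positions came from the RefSeq table of GRCm38.p6, which placed 25027 of the 25131 rows, 24695 by symbol and 332 by a synonym. The table gives gene intervals without strand, exons or transcription start sites. The planned distance to a start site was therefore replaced by the distance from a summit to the nearer end of a protein-coding gene interval, or of the tested gene, within 1 kb, and a peak called near a gene end may lie at the 3′ end. Random positions were drawn 1000 times on the chromosomes of the peaks.

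Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 10241 genes, libraries were scaled by TMM, and KO was compared with WT by the quasi-likelihood test with Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. Fold changes are KO over WT on the log2 scale. Their standard error (SE) was taken from the fold change and the F statistic. CPM are counts per 1e6 counts after TMM scaling, given as mean ± SD of 2 libraries. Where a group held 1 to 3 counts in all, the ratio of the summed counts per depth is given with its exact 95% counting interval. Intervals cover counting error only. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. The replicates of a group differed by more than sampling noise, with a chi-square over its degrees of freedom of 4.78 in WT and 4.22 in KO.

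Before the data were examined, 22 gene lists were fixed and calls were counted per list, adjusted over all genes tested and also adjusted over the list alone. The 21 lists with at least 2 tested members were tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and the p-values were adjusted over the lists. No mitochondrially encoded gene is in the count table. The lists are core pluripotency factors, naive pluripotency, formative and primed pluripotency, genes of two-cell-like cells, neuronal targets of REST and CoREST, neural progenitor and neuronal genes, primitive endoderm, trophoblast, mesoderm and definitive endoderm, germline and meiosis, members of the CoREST and LSD1 complex, ERK targets, WNT targets, LIF and STAT3 targets, imprinted genes, p53 targets, DNA methylation machinery, heat shock and unfolded protein response, fibroblast and feeder cell markers, Y-linked genes, mitochondrially encoded genes and replication-dependent histones. The rule for named genes was also fixed then. It takes Rcor2, Nanog and the called members of the CoREST list, and up to 4 members per list with the lowest p. The rule adds the 12 largest changes in each direction among called genes with a mean log2 CPM of at least 3 and no overlap of the groups. Symbols of the Gm, Rik, AC or BC clone type and calendar dates were left out of these. It also takes the 5 strongest RCOR2 peaks, the RCOR2 peaks at Nanog and the TINC peaks. The overlap of RCOR2 peaks with expression changes was tested by Fisher's exact test, two-sided, and by the exact Cochran-Mantel-Haenszel test within expression quintiles.

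The functions were tested on simulated data before use. In counts simulated for KO against WT over 10241 genes, with 100 genes changed 2-fold and 100 changed 4-fold, 39% of the former and 84% of the latter were called in the right direction, with 3 false calls. Alternatives covered the scaling, the filter on low counts, a replicate block, each library left out, DESeq2 1.42.0, limma-voom, a minimum fold of 1.5, a stricter threshold, chromosomes left out, other list tests, and stricter peak sets, windows and overlaps. The number of calls without the shifted chromosomes was among the alternatives set before. Alternatives that centre each chromosome or leave out Rn45s, and the lists, named genes and peak overlaps without the shifted chromosomes, were chosen after seeing the data, as was the use of gene ends in place of start sites. Figures were drawn with matplotlib 3.10.9.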

Results

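The series asked which proteins sit at the promoter of Nanog, a transcription factor of pluripotent cells, where one of them, the corepressor RCOR2, binds in mouse ESCs, and what its loss does to gene expression. TINC (TALE-mediated isolation of nuclear chromatin) pulls down one locus through a tagged DNA-binding protein (TALE) designed to bind there. RCOR2 is a member of the CoREST family, which works with the histone demethylase LSD1 and histone deacetylases. The data were a peak list for each of 2 TALEs, an RCOR2 peak list and gene counts of 2 Rcor2 KO and 2 WT libraries. The KO libraries held 2951498 and 1974865 counts, and the WT libraries 2368804 and 1286393.

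Both TALEs had a peak at the Nanog promoter. The TALE 1 peak on chromosome 6 from 122707127 to 122707588 was enriched 13.6-fold with a −log10 q of 27.7. The TALE 2 peak from 122707253 to 122707576 lay inside it and was enriched 9.91-fold with a −log10 q of 11.0. Their summits were 146 bp and 43 bp before the start of the Nanog gene interval, which spans 122707489 to 122714633. Of the 13 TALE 1 peaks and 4 TALE 2 peaks, this site was the 1 place shared by both lists.

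Nanog was the strongest of the TALE 2 peaks, but not of the TALE 1 peaks, among which it ranked 3 by −log10 q and 5 by fold. The stronger TALE 1 peaks by −log10 q lay inside the gene of the amino acid transporter Slc6a7 (chromosome 18, 60995779 to 60996212, 15.4-fold) and 35313 bp from Klf13 (chromosome 7, 63974047 to 63974415, 14.0-fold). Peaks inside the potassium channel gene Kcnc1 (chromosome 7, 46422771 to 46423144, 16.2-fold) and the kinase gene Nuak2 (chromosome 1, 132330987 to 132331302, 15.0-fold) also had a higher fold than Nanog. The next lay inside the retinoic acid receptor gene Rarg (chromosome 15, 102247301 to 102247613, 10.6-fold), Inka2 (chromosome 3, 105718462 to 105718736, 11.8-fold) and Zdhhc1 (chromosome 8, 105478913 to 105479144, 11.5-fold). Weaker ones lay inside Rnf41 (chromosome 10, 128411901 to 128412344, 8.10-fold), Tgfb3 (chromosome 12, 86076595 to 86076837, 8.82-fold), Rora (chromosome 9, 69373013 to 69373302, 10.8-fold) and Usp37 (chromosome 1, 74504872 to 74505177, 9.68-fold). The weakest, 5.94-fold, was on chromosome 2 from 159372120 to 159372438, 513900 bp from Dhx35. The other TALE 2 peaks were inside Pde5a (chromosome 3, 122731555 to 122731771, 8.51-fold), 254509 bp from Stpg2 (chromosome 3, 139964684 to 139964898, 7.84-fold) and 223 bp from Pgk1 (chromosome X, 106186791 to 106187065, 5.71-fold). The lists hold 1 value per peak and no replicate values, so the TALEs were not tested against each other.

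RCOR2 bound the Nanog promoter at the site that both TALEs pulled down. The RCOR2 peak on chromosome 6 from 122706925 to 122707636 was enriched 7.58-fold with a −log10 q of 15.4, stronger than 92.5% of all RCOR2 peaks. Stronger RCOR2 peaks lay on either side of Nanog, at 122701446 to 122702894 (10.1-fold, −log10 q of 24.8) and 122720109 to 122720655 (9.64-fold, 22.6), both named after their values were seen. Within 1 kb of Nanog there were 4 more peaks, all weaker. One lay before the gene (122706419 to 122706846, 3.01-fold), and the others inside it (122710134 to 122710648, 4.15-fold; 122711212 to 122711464, 3.69-fold; 122711882 to 122712337, 3.53-fold). Of the 17 TINC peaks, 3 overlapped an RCOR2 peak: the TALE 1 and TALE 2 peaks at Nanog, which are 1 site, and the TALE 1 peak in Rnf41.

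**Figure D1:**
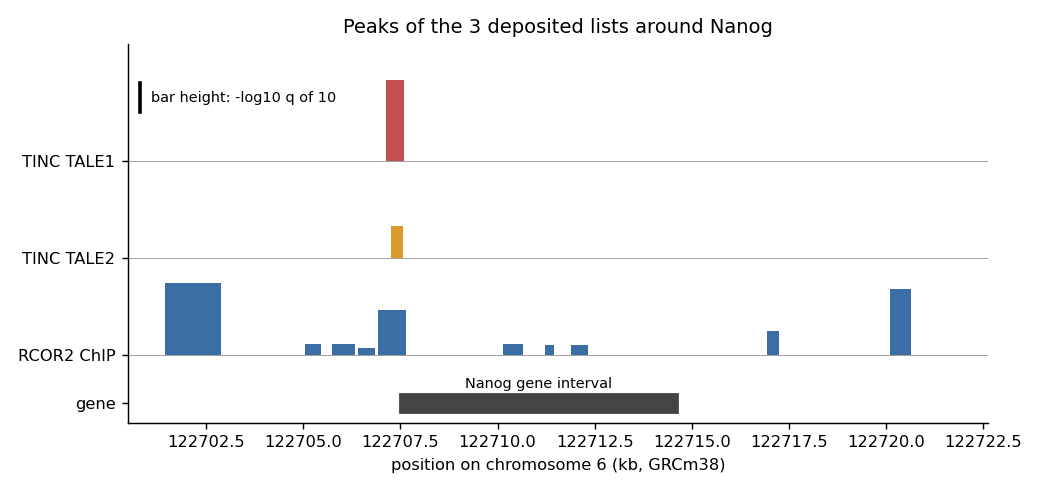
Map of chromosome 6 around Nanog, with position in kb on GRCm38 on the horizontal axis and 1 row for each peak list. Bars span the peaks and their height is the −log10 q; the grey bar is the Nanog gene interval. The TALE 1 peak, the TALE 2 peak and an RCOR2 peak with a −log10 q of 15.4 overlap at the start of the interval.

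Across the genome the RCOR2 list held 53366 peaks, with a median width of 260 bp and a median fold of 4.38. The list was deposited as raw peaks, with a −log10 q down to 1.31, so it includes weak peaks. Summits within 1 kb of an end of a protein-coding gene made up 22.7% of the peaks (12108; Wilson 95% interval 22.3% to 23.0%). Random positions gave 3.17%, and at most 3.41% in 1000 draws. A further 31.7% lay deeper inside genes and 45.6% elsewhere. Peaks near a gene end had a median −log10 q of 4.46 and the rest 5.16.

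The strongest peak by −log10 q, 285, lay on the contig of the HA-tagged Rcor2 construct itself. The next was on chromosome 10 from 126680170 to 126681784, 49.6-fold enriched and 186658 bp from the nearest gene, Atp23. The third lay in Rcor2 on chromosome 19 from 7273997 to 7274700, 35.1-fold enriched, 734 bp from the end of the gene interval. There, reads of the tagged construct cannot be told from binding. The 2 peaks that followed in rank, each 42.8-fold enriched, lay on chromosome 4. One was inside Camta1, a transcription factor gene (151604114 to 151605492). The other was 12178 bp from Igsf21 (140258723 to 140259825). The number of peaks depended on the threshold: 26702 had a −log10 q of at least 5 and 17972 a fold of at least 5.

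In the KO libraries Rcor2 itself was counted 157 and 103 times, and in the WT libraries 193 and 107 times. This was 54.0 ± 0.212 CPM in the KO and 81.4 ± 0.117 CPM in WT (SD, n = 2), a log2 fold change of −0.59 (SE 0.23) that missed the threshold (edgeR, adjusted p = 0.0636). The labels do not say which part of the gene was deleted, so these counts do not check the genotype. Nanog was higher in the KO, at 630 ± 15.4 CPM against 451 ± 0.00613 CPM, a log2 fold change of 0.48 (SE 0.15; edgeR, adjusted p = 0.0127). That call was lost when either KO library was left out (0.46 without replicate 1 and 0.51 without replicate 2). Nanog lies on chromosome 6, whose 502 tested genes had a median change of 0.92, and centred on that median Nanog was at −0.44 (SE 0.15), called lower in place of higher (edgeR, adjusted p = 0.0361). Without centring, the adjusted p ran from 0.00465 to 0.165 over the alternatives (edgeR, DESeq2 or limma-voom).

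**Figure D2:**
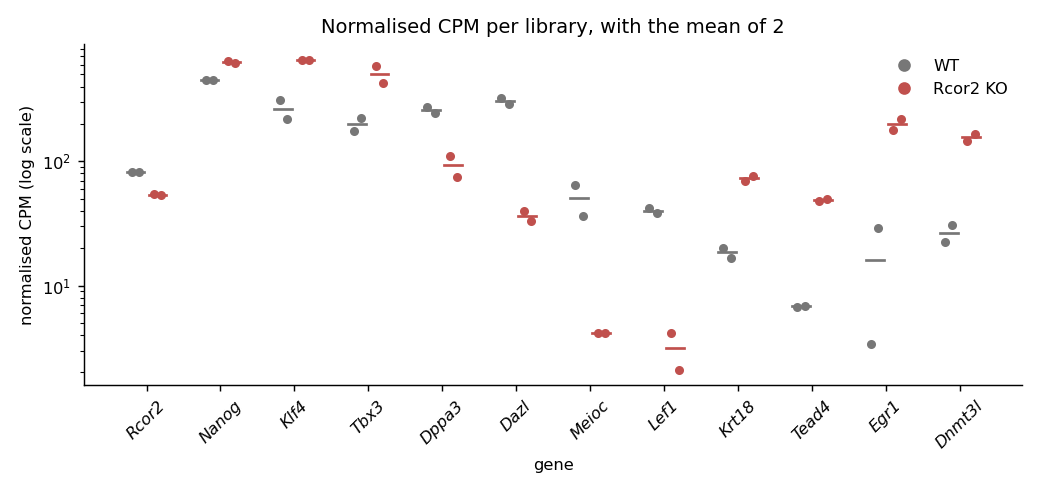
Normalised CPM (log scale) of 12 named genes in the 2 WT libraries (grey) and the 2 Rcor2 KO libraries (red); horizontal lines are group means. The KO points of Dazl, Meioc and Lef1 lie below the WT points, those of Tead4, Krt18 and Dnmt3l above, and Rcor2 remains detected in the KO at 54.0 CPM.

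In the KO the lists of germline genes were called lower and those of trophoblast genes, primitive endoderm genes and ERK targets higher by camera, with members of both directions among trophoblast genes and ERK targets. Each of these calls was lost with an estimated correlation (camera, adjusted p = 0.386). That form of the test also missed a planted 2-fold change of 25 genes in simulated data (camera, adjusted p = 0.127). The loss therefore cannot decide on these lists. Nor can the simulation, in which genes varied independently. In all, 1062 genes were higher and 952 lower in the KO among 10241 tested (edgeR, adjusted p under the threshold). Of the largest increases, Trh, the thyrotropin-releasing hormone, rose by 5.14 on the log2 scale (SE 0.52), Egr1, an immediate early transcription factor, by 3.87 (SE 0.32), Gpnmb by 4.25 (SE 0.70), the lipoprotein Apom by 3.97 (SE 0.67), Pianp by 3.99 (SE 0.74) and the unnamed locus LOC105246506 by 3.99 (SE 0.56). Other genes were near absent in WT, so the ratio of summed counts is given. It was 56.7 for the homeobox gene Tlx2 (95% interval 9.87 to 2270), 55.9 for Pdgfrl (9.73 to 2239), 30.7 for Prss35 (8.21 to 257), 30.9 for the growth factor Fgf10 (10.3 to 152), 16.3 for Pon3 (5.35 to 81.4) and 15.3 for Capn2 (5.00 to 76.4). For each of these genes all WT counts came from 1 of the 2 WT libraries, and with that library left out the size of change moved by over 1.5 times. Among the largest decreases, Cyct, the testis form of cytochrome c, was at −4.03 on the log2 scale (SE 0.20) and the germ cell transcription factor Dmrt1 at −4.08 (SE 0.64). Elobl was at −4.05 (SE 0.69), Epb41l3 at −3.79 (SE 0.80), Plxdc2 at −3.74 (SE 0.78), Tbc1d9 at −3.70 (SE 0.69), the epoxide hydrolase Ephx2 at −3.69 (SE 0.41) and Rbm44 at −3.63 (SE 0.60). Fam183b went from 17.9 ± 8.06 to 1.04 ± 0.00772 CPM (SD, n = 2). Sizes of change moved with the libraries: without WT replicate 1 and 2, Egr1 was at 2.80 and 5.86 and Apom at 3.29 and 4.66. Without KO replicate 1 and 2, Dmrt1 was at −3.06 and −6.05, Elobl at −3.07 and −5.81, Epb41l3 at −7.78 and −3.04 and Rbm44 at −8.70 and −2.85, and Ephx2 was at −4.75 without KO replicate 1. The numbers of calls moved with the test and the libraries: DESeq2 called 1156 genes, and edgeR called 1130 and 1126 without KO replicate 1 and 2. DESeq2 did not call Rbm44 (adjusted p = 0.176) or the germline gene Mov10l1 (0.124), nor, among the genes named below, Lin28a, Dnmt3a, Nefl, Nes, Fos, Znrf3, Tcf7 and Ccng1.

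Genes of chromosomes 6, 8 and 3 were shifted up and those of chromosome 11 down as a whole. The median log2 fold change was 0.92 on chromosome 6 (282 genes higher and 12 lower of 502), 0.52 on chromosome 8 (166 and 10 of 565), 0.48 on chromosome 3 (126 and 26 of 480) and −0.49 on chromosome 11 (17 and 271 of 870). The other autosomes and X had medians between −0.16 and −0.00. Of the genes with the largest increases, Trh, Gpnmb, Pianp, Tlx2 and Pon3 lie on chromosome 6; centred on it, Trh was at 4.24, Gpnmb at 3.36 and Pianp at 3.09. The Y-linked genes Eif2s3y and Ddx3y were counted once each over both KO libraries. Eif2s3y, a translation initiation factor gene, was 128 times as high in WT by summed counts (95% interval 22.4 to 5102), and the RNA helicase Ddx3y 52.2 times (8.85 to 2113). Without KO replicate 1 and 2, Eif2s3y was at −8.60 and −6.02 on the log2 scale and Ddx3y at −4.30 and −7.67. These chromosomes held 23.6% of the tested genes and 45.3% of the calls. With them left out, 399 genes were higher and 549 lower (edgeR), so that 42.1% of the calls were higher in place of 52.7%.

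**Figure D3:**
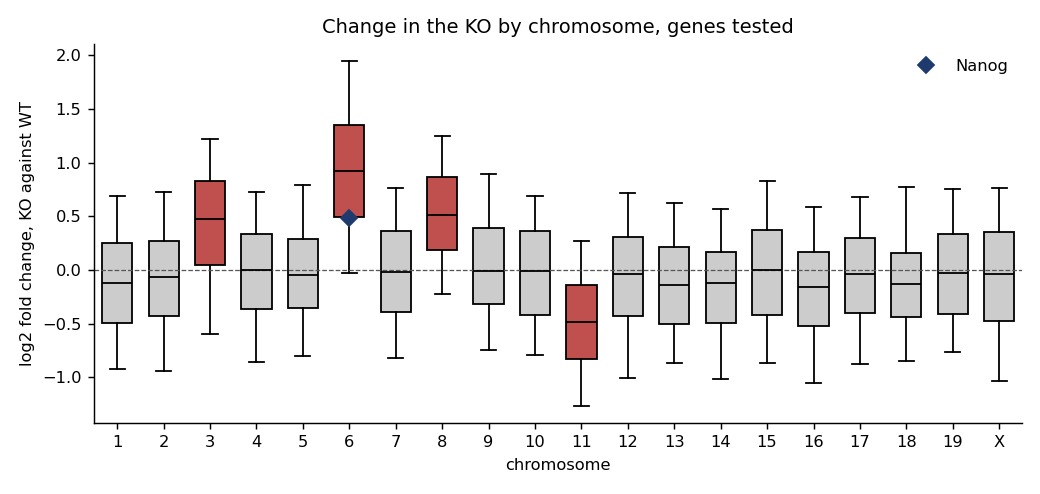
Log2 fold change of KO against WT for the genes tested on each autosome and X; boxes span the quartiles, the line is the median and whiskers reach the 10th and 90th percentiles. The red boxes are chromosomes 3, 6, 8 and 11, with medians of 0.48, 0.92, 0.52 and −0.49, and the diamond is Nanog at 0.48.

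Germline and meiosis genes had the lowest adjusted p of the lists by camera with the preset correlation. Of 25 tested members 12 fell and 0 rose, or 16 and 0 adjusted over the list alone (camera, adjusted p = 9.82e-10; adjusted p = 0.386 with an estimated correlation). The germ cell RNA-binding protein Dazl fell from 307 ± 22.8 to 36.3 ± 4.76 CPM (SD, n = 2), a log2 fold change of −3.07 (SE 0.19; edgeR, adjusted p = 2.07e-19). The meiosis gene Meioc (−3.60, SE 0.42), the meiotic cohesin subunit Smc1b (−2.24, SE 0.27) and Mov10l1, a helicase of the piRNA pathway (−3.72, SE 0.68), fell as well. Mov10l1 was at −2.95 without KO replicate 2 and at −8.35 without KO replicate 1. Of the 25 members, 10 lie on the shifted chromosomes. With each chromosome centred 12 were again called lower, with Hormad1 in place of Tex19.2, both named after their values were seen.

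Of 16 trophoblast genes 8 were tested, of which 6 rose and 2 fell, the same adjusted over the list alone (camera, adjusted p = 0.00785; adjusted p = 0.386 with an estimated correlation). The trophectoderm transcription factor Tead4 rose by 2.84 on the log2 scale (SE 0.39), Gata2 by 3.05 (SE 0.52) and the keratin Krt18 by 1.95 (SE 0.29), while Tfap2c fell by 1.44 (SE 0.25). The other member that fell was Esx1 (−2.48, SE 0.43). Cdx2, Elf5 and Hand1 were too low to be tested, with at most 8 counts in a library. These 4 genes were named after their values were seen. Tead4 and Gata2 lie on chromosome 6 and were at 1.93 and 2.14 centred, with 6 higher and 2 lower members still called. The list kept its call with chromosomes centred (camera, adjusted p = 0.0110) and lost it with the genes of the shifted chromosomes left out (0.0686). Of 20 primitive endoderm genes 9 were tested, of which 4 rose and 0 fell, or 5 and 0 adjusted over the list alone (camera, adjusted p = 0.00785; adjusted p = 0.386 with an estimated correlation). Those that rose included the laminin chains Lama1 (1.69, SE 0.32) and Lamc1 (1.16, SE 0.22), as well as Dab2 (1.72, SE 0.42) and Lrp2 (1.63, SE 0.42). Gata6, Gata4, Sox17, Sox7, Pdgfra and Foxa2, named after their counts were seen, were too low to be tested. They had at most 12 counts in a library. The calls of Dab2 and Lrp2 were lost without KO replicate 1 (1.29 and 1.36), and that of Dab2 without WT replicate 1 (1.24). Of mesoderm and definitive endoderm genes 1 of 6 rose, also adjusted over the list alone (camera, adjusted p = 0.955). It was the T-box factor Eomes, at 19.9 ± 3.70 against 2.16 ± 1.26 CPM, with Lefty1 at −1.14 (SE 0.49), Gsc at −1.12 (SE 0.54) and Lefty2 at 0.15 (SE 0.20).

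The pluripotency genes moved both ways. Of naive pluripotency genes 6 rose and 3 fell of 17, or 7 and 3 adjusted over the list alone (camera, adjusted p = 0.312). Off the shifted chromosomes 5 rose and 1 fell, and the list without those chromosomes was called higher (camera, adjusted p = 0.00766). With chromosomes centred 5 were called higher and 4 lower, and the list was not called (camera, adjusted p = 0.473). The transcription factor Tbx3 rose by 1.37 on the log2 scale (SE 0.16) and Klf4 from a mean of 265 to 657 CPM (edgeR, adjusted p = 3.44e-09). Dppa3, a maternal factor also made in ESCs (−1.47, SE 0.18; −2.39 centred on chromosome 6), and the adhesion molecule Pecam1 (−1.58, SE 0.22) fell. Of core factors 2 rose and 1 fell of 12, or 3 and 3 adjusted over the list alone (camera, adjusted p = 0.554); with chromosomes centred 1 was called higher and 3 lower. Sox2 on chromosome 3, named after its values were seen, was at −0.24 (SE 0.14) and was called lower centred (−0.72). Besides Nanog these were the growth factor Fgf4, which fell by 0.83 (SE 0.16), and the RNA-binding protein Lin28a, at 1.34 (SE 0.47; edgeR, adjusted p = 0.0354), whose call was lost without either KO library or WT replicate 1 (1.06 to 1.36), with library size alone (1.29), and with the genes of the shifted chromosomes left out (edgeR, adjusted p = 0.0506). Sall4 was at −0.42 (SE 0.17), and was called without KO replicate 1 (−0.80), without WT replicate 1 (−0.60) and by limma-voom (−0.40). Formative and primed genes fell in 4 of 9 and rose in 0, the same adjusted over the list alone (camera, adjusted p = 0.0239; adjusted p = 0.386 with an estimated correlation). The WNT-responsive factor Lef1 fell from 40.1 ± 2.87 to 3.12 ± 1.45 CPM. Zic2 was at −0.91 (SE 0.24), Sox4 at −1.30 (SE 0.35) and the DNA methyltransferase Dnmt3a at −1.03 (SE 0.29). These 3 calls were each lost with a library left out: Zic2 without KO replicate 2 (−0.82) or WT replicate 2 (−0.68), Sox4 without WT replicate 1 (−1.13) and Dnmt3a without WT replicate 2 (−0.49). The call of the list was lost without WT replicate 2 (camera, adjusted p = 0.0561).

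**Figure D4:**
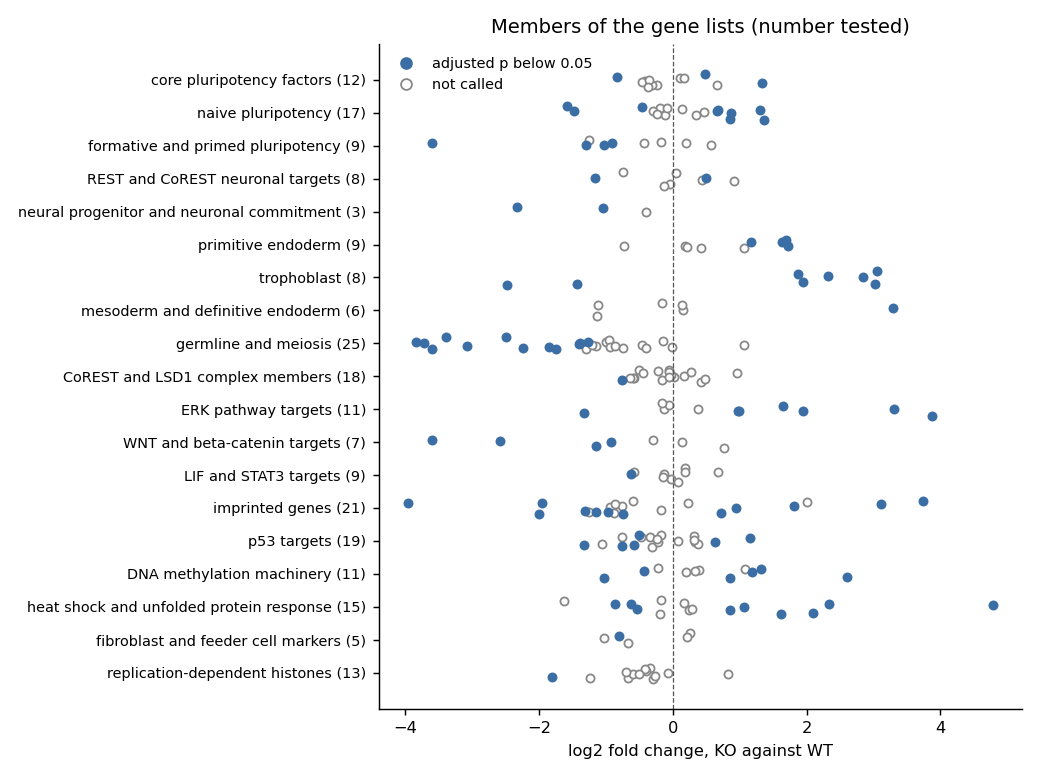
Log2 fold change of KO against WT (horizontal axis) for each tested member of the gene lists with at least 3 tested members, whose number is in brackets; filled points passed an adjusted p of 0.05 in edgeR. Germline members lie to the left except for 1 (Piwil2), with 12 of 25 filled, and 6 of the 8 trophoblast members lie to the right.

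Of ERK targets, which MAP kinase signalling induces, 6 rose and 1 fell of 11, the same adjusted over the list alone (camera, adjusted p = 0.0210; adjusted p = 0.386 with an estimated correlation). Egr1 was at 199 ± 27.5 CPM in the KO against 16.2 ± 18.1 in WT. The immediate early gene Ier2 rose by 0.99 (SE 0.19), Fos was at 1.65 (SE 0.35), and the ETS factor Etv5 fell by 1.32 (SE 0.22). The call of Fos was lost without WT replicate 1 (0.72) and that of Ier2 after centring on chromosome 8 (0.48). Dusp6 (−0.13), Spry1 (0.38), Spry2 (−0.06) and Ccnd1 (−0.16), named after their values were seen, were not called. Of 12 WNT targets 7 were tested, of which 4 fell and 0 rose, the same adjusted over the list alone (camera, adjusted p = 0.0210; adjusted p = 0.403 with an estimated correlation). Of the tested members 6 lie on the shifted chromosomes. With chromosomes centred 2 were called lower and 0 higher (camera, adjusted p = 0.0383). Besides Lef1, the secreted WNT inhibitor Notum was at −2.59 (SE 0.58), Znrf3 at −1.14 (SE 0.32) and Tcf7 at −0.92 (SE 0.30). These 3 lie on chromosome 11, and the calls of Znrf3 and Tcf7 were lost after centring (−0.66 and −0.43), without KO replicate 2 (−0.89 and −0.55), and without WT replicate 2 (−0.86) or WT replicate 1 (−0.82). The list's call was lost without WT replicate 2 (camera, adjusted p = 0.0771) and without a filter on low counts (0.101).

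Of LIF and STAT3 targets 1 of 9 changed, also adjusted over the list alone (camera, adjusted p = 0.759). It was Ifitm3, at −0.62 (SE 0.15), lost without KO replicate 2 (−0.60), with Junb at 0.68 (SE 0.48), Jak3 at −0.57 (SE 0.73) and Stat3 at 0.18 (SE 0.23). Stat3 on chromosome 11 was called higher centred (0.66).

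Genes of the DNA methylation machinery rose in 4 and fell in 2 of 11, or 5 and 2 adjusted over the list alone (camera, adjusted p = 0.0422; adjusted p = 0.545 with an estimated correlation; 0.244 with chromosomes centred). Dnmt3l, the cofactor of the de novo methyltransferases, rose from 26.4 ± 5.75 to 157 ± 13.9 CPM. The hydroxymethylating enzyme Tet2 was at 0.86 (SE 0.18) and Gadd45a at 1.19 (SE 0.28), and both calls were lost after centring (0.39 and 0.27). That of Tet3 on chromosome 6, named after its values were seen, was lost as well (1.31 and 0.40 centred), so that 1 member was called higher and 2 lower with chromosomes centred. The call of Gadd45a was also lost without KO replicate 1 (0.71) or WT replicate 1 (0.75), and that of the list without KO replicate 1 (camera, adjusted p = 0.0518), without WT replicate 1 (0.229), with library size alone (0.0602) and with the filter of 10 CPM (0.0556). Of imprinted genes 5 rose and 7 fell of 21, or 6 and 8 adjusted over the list alone (camera, adjusted p = 0.343). The neighbouring paternally expressed genes Peg10 and Sgce on chromosome 6 rose by 3.73 (SE 0.30) and 3.11 (SE 0.48), and were at 2.82 and 2.19 centred. The maternally expressed noncoding RNA Meg3 (−3.95, SE 0.59) and the amino acid transporter Slc38a4 (−1.95, SE 0.32) fell.

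Neuronal genes were little detected. Of the neuronal targets of REST and CoREST 8 of 36 were tested, 1 rose and 1 fell, the same adjusted over the list alone (camera, adjusted p = 0.775). Stmn2 was at 0.50 (SE 0.15) and the neurofilament gene Nefl at −1.16 (SE 0.37), with calls lost after centring (0.03 and −1.04) and without KO replicate 1 (0.52 and −0.96). The call of Stmn2 was also lost without KO replicate 2 (0.49) or WT replicate 2 (0.31) and that of Nefl without WT replicate 1 (−0.92). Ina was at 0.92 (SE 0.63) and Unc13a at −0.74 (SE 0.68). Of neural progenitor and neuronal genes 2 of 3 fell, or 3 adjusted over the list alone (camera, adjusted p = 0.0422; adjusted p = 0.545 with an estimated correlation; 0.103 with chromosomes centred). They were Olig2, at −2.32 (SE 0.57), and Nes, at −1.04 (SE 0.38), with Mapt at −0.40 (SE 0.19). The calls of Olig2 and Nes were lost without WT replicate 1 (−1.98 and −0.78), that of Nes without KO replicate 1 (−0.39), and that of the list without KO replicate 1 (camera, adjusted p = 0.183), without WT replicate 1 (0.195) and with the filter of 10 CPM (0.0556). The call of Nes was also lost with library size alone (−1.10).

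Of the CoREST and LSD1 complex 1 of 18 members changed, also adjusted over the list alone (camera, adjusted p = 0.385). It was the corepressor Ctbp2, at −0.75 (SE 0.18), lost without KO replicate 2 (−0.65). Hdac2 was at −0.51 (SE 0.21), and was called without WT replicate 1 (−0.70). Heat shock and unfolded protein response genes rose in 6 and fell in 3 of 15, the same adjusted over the list alone (camera, adjusted p = 0.115). The list was called without a filter on low counts (camera, adjusted p = 0.0145) and without either WT library (0.0171 for each). Asparagine synthetase (Asns) on chromosome 6 rose by 1.61 (SE 0.14; 0.70 centred), its regulator Atf4 by 1.07 (SE 0.18) and Herpud1 by 2.09 (SE 0.38), and the chaperone Hsph1 fell by 0.86 (SE 0.19). Of p53 targets 2 rose and 4 fell of 19, the same adjusted over the list alone (camera, adjusted p = 0.349). Pmaip1 was at 0.63 (SE 0.17), Polk at −1.33 (SE 0.37), Phlda3 at 1.15 (SE 0.33) and Ccng1 at −0.50 (SE 0.16), and each of these calls was lost without KO replicate 1 (0.58, −1.24, 1.19 and −0.59). Ccng1 lies on chromosome 11, and its call was also lost after centring (−0.0185) and without the filter on low counts (−0.48). The calls of Phlda3 and Ccng1 were lost without KO replicate 2 (1.11 and −0.43), those of Pmaip1 and Phlda3 without WT replicate 1 (0.39 and 1.07), and those of Polk and Ccng1 without WT replicate 2 (−1.11 and −0.34).

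Of fibroblast and feeder cell markers 5 of 23 were tested and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.372). It was the matrix protein Fn1, which fell by 0.80 (SE 0.16), with Col1a1 at −1.02 (SE 0.64), Sparc at 0.21 (SE 0.14) and Timp3 at −0.66 (SE 0.50). Sparc on chromosome 11 was called higher centred (0.69) and Timp3 lower without WT replicate 1 (−1.40). Of replication-dependent histones 1 of 13 fell, also adjusted over the list alone (camera, adjusted p = 0.0756). It was Hist1h2bc, at −1.80 (SE 0.51), lost without KO replicate 2 (−1.46) or WT replicate 1 (−1.64). The list was called lower without KO replicate 1 (camera, adjusted p = 0.0189) or WT replicate 1 (0.0388). Hist1h4d was at −0.50 (SE 0.20). It was called without KO replicate 1 (−1.04) or WT replicate 2 (−0.55), with the replicate block (−0.56) and by limma-voom (−0.54). Hist1h1e was at −0.67 (SE 0.38) and Hist1h4c at −1.23 (SE 0.71). Of genes of two-cell-like cells 2 of 26 were tested and 0 were called by edgeR, also adjusted over the list alone and by DESeq2 (camera, adjusted p = 0.824): Eif1a was at 0.11 (SE 0.15) and Zfp750 at −0.90 (SE 0.64). Both tested Y-linked genes fell, also adjusted over the list alone (camera, adjusted p = 0.00624; adjusted p = 0.386 with an estimated correlation). In all, 9 of the 21 lists were called, 4 higher and 5 lower, and 0 with an estimated correlation. With the shifted chromosomes left out 17 lists could be tested, and camera also lost the call of formative and primed genes (adjusted p = 0.128) and the DNA methylation machinery (0.370). It then called naive pluripotency higher (camera, adjusted p = 0.00766) and imprinted genes lower (0.0260). The fry test (limma) asks another question, whether the members of a list changed in a common direction, and does not compare them with the other genes. By it the lists of formative and primed genes (adjusted p = 0.0518), neural genes (0.110), ERK targets (0.105), WNT targets (0.0658) and the DNA methylation machinery (0.123) missed the threshold, and those of two-cell-like cells, with 2 tested genes, and of heat shock genes passed it (0.0106 for each). Some sizes of change in these lists moved by over 1.5 times with a library left out, with calls kept. Without WT replicate 1 and 2, Eomes was at 2.69 and 3.91 and Sgce at 2.18 and 4.44. Without WT replicate 1, Gata2 was at 3.65, Herpud1 at 3.03 and Lrp2 at 2.56, and without WT replicate 2 Fos was at 3.40. Without KO replicate 1, Lef1 was at −4.22, Notum at −3.67 and Meg3 at −5.62, and without KO replicate 2 Meg3 was at −3.37 and Nes at −2.03. In simulated data camera with an estimated correlation gave a planted 2-fold change of 25 genes an adjusted p of 0.127. With the preset correlation it gave 3.58e-29. The genes were simulated independently, so how often the preset form calls correlated lists falsely was not tested. A call lost with an estimated correlation therefore leaves the list undecided.

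An RCOR2 peak at a gene was not tied to a higher share of changed genes by the tests used. Of 10215 tested genes with a position, 6877 (67.3%) had a summit within 1 kb of an end. Among them 10.6% were higher in the KO against 9.77% of the others, an odds ratio of 1.10 (95% interval 0.954 to 1.26; Fisher's exact test, two-sided, p = 0.188, adjusted over both directions 0.376). The lower genes were 9.15% against 9.68%, an odds ratio of 0.94 (0.815 to 1.09; Fisher's exact test, p = 0.384, adjusted 0.384). Within expression quintiles the odds ratios were 0.99 (0.858 to 1.14) for higher and 0.895 (0.775 to 1.04) for lower genes (exact Cochran-Mantel-Haenszel test, p = 0.886 and 0.130, adjusted 0.886 and 0.261). Of the gene groups above, trophoblast genes had a peak in 1 of 8, and germline genes in 16 of 25. LIF and STAT3 targets had one in 9 of 9, and the CoREST and LSD1 complex in 15 of 18. Among single genes, Nanog, Klf4, Tbx3, Dppa3, Dazl, Meioc and Egr1 had a peak at an end and Trh, Cyct, Pecam1, Lef1, Krt18, Gata2 and Dnmt3l had none there. Rcor2 had one too, but reads of the tagged construct cannot be told from binding at that gene. The odds ratio of higher genes was 1.21 with DESeq2 calls, without KO replicate 2 and without WT replicate 2, and passed the threshold adjusted over both directions without WT replicate 2 alone (Fisher's exact test, adjusted p = 0.0194), and not within expression quintiles. Genes are not independent replicates, so these tests describe the overlap of gene sets.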

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

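All of the tests in this part were chosen after the results they bear on were seen. The RCOR2 list held a peak on the contig of the HA-tagged Rcor2 construct, a sequence that no comparison used, with a −log10 q of 285, the highest of the whole list.

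Genes of chromosomes 3, 6 and 8 were higher and those of chromosome 11 lower in both KO libraries. Depth or normalization did not account for it, since the WT libraries differed by at most 0.0266 on these chromosomes. Genes with no RCOR2 summit within 1 kb of an end departed by at least 0.435 on each. The medians of genes with and without such a summit were 0.477 and 0.476 on chromosome 3 and 0.865 and 0.987 on chromosome 6. They were 0.507 and 0.602 on chromosome 8 and −0.491 and −0.474 on chromosome 11. Loss of RCOR2 at gene ends alone therefore did not account for the shift. Such genes can hold RCOR2 peaks deeper inside or further away, so loss of RCOR2 there was not excluded. A difference in copy number of whole chromosomes between the KO and WT cells stays open and is consistent with the test, in which each of 16 segments, 4 per chromosome, departed by at least 0.395 in the direction of its chromosome. Both tested Y-linked genes were also near absent in the KO. Eif2s3y had 68 and 30 counts in the WT libraries and 1 and 0 in the KO libraries, and Ddx3y 20 and 20 against 0 and 1. DNA of the KO cells was not sequenced in the libraries used here, so copy number was not measured. As a hypothesis, part of the KO difference may therefore belong to the cell line and not to Rcor2.

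Nanog was higher in the KO by 0.48 on the log2 scale, which a direct effect of RCOR2 at its promoter or the shift of chromosome 6 could give. Nanog did not rise beyond the genes of its chromosome, as it lay at percentile 24.3 of the tested genes there. A direct effect of RCOR2 on Nanog cannot be decided by this, since copy number was not measured. The shift of the chromosome, with a median of 0.92, was large enough to give the rise. That shift alone would leave no difference after centring, but Nanog was then at −0.44, called lower than its chromosome (edgeR, adjusted p = 0.0361). Whether the loss of RCOR2 gives that lower value was not tested.

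Strong RCOR2 peaks lay inside the Rcor2 gene, 4 of them with a −log10 q of at least 30. Reads of the tagged construct placed on the gene fit this, since the highest −log10 q in the 20 kb on either side was 25.9. RCOR2 bound at its own gene cannot be told apart from it: the strongest summit was 734 bp from the end of the gene, and the gene table gives no exon positions.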

How the results depend on the processing

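The alternatives that centre chromosomes or leave out Rn45s were chosen after seeing the data, as were the gene lists and peak overlaps without the shifted chromosomes; with a library left out, the lone sample is assumed to vary like the other group. Of 76 called genes named here, 52 kept their direction and call wherever they were tested under the other scalings, filters, tests, replicate block and left-out libraries, and 67 after centring; the minimum fold and the stricter threshold were counted over all genes alone. Against 2014 calls (1062 higher, 952 lower), DESeq2 gave 1156 (650 and 506), centring 1328 (643 higher), the fit without the shifted chromosomes 948 (399 and 549), a minimum fold of 1.5 gave 639 (366 and 273), an adjusted p under 0.01 gave 1186 (671 and 515), and leaving out a library 1126 to 1738 (616 to 948 and 495 to 790). The replicate block gave 1822 calls, but libraries with the same number did not pair (correlation of their deviations −0.0532). Rcor2 passed the threshold with library size alone (−0.64); Nanog ranged from 0.46 to 0.51 with a library left out and was −0.44 centred. Camera called 0 lists with an estimated correlation and 5 of the 17 that could be tested without the shifted chromosomes, against 9 of 21. The form with an estimated correlation also missed a planted list in simulated data, so its 0 calls cannot decide on the lists. The simulation held no correlated genes, so it does not vouch for the preset form either. Genes that missed the threshold turned direction: Mapt when centred (0.0855) and, with a library left out, Eif1a (−0.0201 to 0.24), Jak3 (−1.04 to 0.43), Stat3 (−0.0503 to 0.52) and Timp3 (−1.40 to 0.57). So did uncalled lists, by adjusted p: two-cell-like genes when centred (0.841), REST targets without a filter (0.800), when centred (0.851) and with a library left out (0.436 to 0.990), mesoderm and definitive endoderm by fry (0.964, a test against no change and not against other genes) and with a library left out (0.861 to 0.934), and imprinted genes with a library left out (0.152 to 0.823). RCOR2 peaks numbered 26702 at a −log10 q of at least 5, with 21.7% near a gene end, and 17972 at a fold of at least 5, with 21.4%; 38.9% were within 5 kb. At a −log10 q of at least 5, TALE 2 kept 2 peaks. The odds ratio of higher genes was 1.21 with DESeq2 calls, 0.991 without the shifted chromosomes and 1.02 to 1.21 with a library left out; that of lower genes was 1.07 at a −log10 q of at least 5, 1.04 with DESeq2 calls and 0.929 to 1.04 with a library left out. Within expression quintiles the ratio of higher genes was 1.02 within 5 kb, 1.00 at a −log10 q of at least 5, 1.04 for the strongest 13554 peaks, 1.05 with DESeq2 calls, 1.00 with the replicate block and 0.892 to 1.09 with a library left out, and that of lower genes 1.05 at a −log10 q of at least 5. Fewer genes, libraries or peaks account for the lower counts by construction; otherwise the cause was not tested. The smallest library held 1286393 counts, and at these depths and 2 libraries per group 39% of simulated 2-fold changes were recovered; how depth alone limits this was not tested.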

Other observations

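The gene lists of this part and their tests were chosen after seeing the data, as were the genes named. The p-values, adjusted over the 3 lists of this part, therefore describe the lists and are not independent tests of them. Glycolysis genes rose in 8 of 21 and fell in 3 (camera, adjusted p = 0.00873; adjusted p = 0.141 with an estimated correlation). The glucose transporters Slc2a3 and Slc2a1 rose by 1.90 (SE 0.15) and 1.07 (SE 0.17) on the log2 scale, the pyruvate dehydrogenase kinase Pdk1 by 1.03 (SE 0.27) and the lactate dehydrogenase subunit Ldha by 0.65 (SE 0.14), while the other subunit, Ldhb, fell by 1.29 (SE 0.19). Of the genes that rose, 4 lie on the shifted chromosome 6: centred on it, Slc2a3 was at 0.98 and Tpi1 at 0.85, and Hk2 (0.41) and Gapdh (−0.0290) lost their calls. Ldhb, also there, was at −2.21. With chromosomes centred 6 members were called higher and 2 lower, and the list had an adjusted p of 0.0381 (camera). Genes of the amino acid response, which the transcription factor ATF4 drives, rose in 7 of 22 and fell in 2. The list was drawn up after Asns and Atf4, which it holds, had been seen to rise, so no test of it is given. Besides these, Nupr1, a stress-induced nuclear protein, rose by 2.36 (SE 0.20), Cth, which makes cysteine, by 1.71 (SE 0.22; 1.23 centred on chromosome 3), and Slc3a2, a subunit of amino acid transporters, by 0.62 (SE 0.16). With chromosomes centred 6 members of this list were called higher and 2 lower. Mthfd2 on chromosome 6 lost its call (1.13 before and 0.21 after), as did Cebpg (−1.20 and −1.19), and Phgdh on chromosome 3 was called lower (−0.57 and −1.05). Of cholesterol synthesis genes 0 rose and 3 fell of 21, namely Hmgcs1, Stard4 and Hsd17b7 (camera, adjusted p = 0.259). With chromosomes centred none of the 3 passed the threshold, with Hmgcs1 at −0.60 before and −0.45 after, Stard4 at −0.80 and −0.67, and Hsd17b7 at −1.04 and −0.92.

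The share of counts on the ribosomal RNA gene Rn45s was 1.82% and 2.44% in the KO libraries and 2.08% and 3.51% in the WT libraries. The correlation of log2 CPM was 0.949 between the WT libraries and 0.961 between the KO libraries, and 0.886 to 0.899 between groups.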
